A study of Triticum aestivum with 6 samples.

How the data were processed

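RNA-seq of flag leaves from field plants of bread wheat (Triticum aestivum) was available for 3 cultivars with 2 libraries each: ZM895, resistant to stripe rust, and JM22 and MX169 (Mingxian 169), both susceptible. The labels give all 6 samples as inoculated with the stripe rust fungus and name a tissue and cell type but no field plot, day or batch. Libraries were grouped by cultivar from the sample titles and the design given with the series.

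The deposited table holds, for each gene and library, a read count and an FPKM value, both computed by the authors. The read counts are whole numbers with no normalization (unit: counts, per the file headers). The FPKM values by the authors equal, for every gene above 0, the count per kilobase of the listed gene length scaled by the total count of the library, within 0.01 percent. The aligner, the genome build and the counting program are not given in the sources used here. Genes carry TraesCS identifiers, coordinates, GO and KEGG terms and descriptions. The table holds 107545 genes, of which 35083 had no read in any library. A further 468 lines that name no gene and hold no value, left by line breaks in the annotation, were left out. A separate table of gene symbols was not used because 0 of its identifiers match.

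Library totals were 23384575 and 24818039 counts in ZM895, 20286599 and 21659672 in JM22, and 18151478 and 21171228 in MX169. Across genes, log counts of the replicates, scaled for depth, correlated at 0.973 in ZM895, 0.973 in JM22 and 0.957 in MX169, and libraries of different cultivars at 0.728 to 0.816; genes are not independent replicates. The spread between replicates was 11.3 to 19.7 times that of counting error alone (chi-square per degree of freedom), so depth limits mainly genes with few reads. For genes at 0 counts in a cultivar the difference is given as a lower bound, against a floor of 3 counts over the group. For 1 to 3 counts it is a ratio of counts scaled for depth, with an exact 95 percent interval. Intervals and floors cover counting error only.

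Genes with at least 1 FPKM in at least 2 of the 6 libraries were tested, 43580 genes that hold at least 98.9 percent of the counts of each library. The test was edgeR quasi-likelihood on the counts (edgeR 4.0.16, R 4.3.3) with TMM scaling, an abundance trend and 1 mean per cultivar, so all comparisons share 1 estimate of the spread with 3 residual degrees of freedom (common biological coefficient of variation 0.207, prior degrees of freedom 4.94). Contrasts were ZM895 against JM22, ZM895 against MX169, JM22 against MX169, and ZM895 against the mean of the other two. P-values were adjusted by Benjamini-Hochberg within a comparison, and a call is an adjusted p under 0.05; calls with an absolute log2 difference of at least 1 were also counted. A limma test on log2(FPKM + 1) had been planned; since the table turned out to hold counts, the count test became the main one and the limma test (limma 3.58.1) an alternative. On simulated data with 200 genes changed per comparison, none of them with few counts, 12 to 18 percent of those changed 2-fold and 82 to 84 percent of those changed 4-fold were called. Far fewer genes were changed than were called in the data, which makes the adjusted threshold stricter. These shares therefore do not give the recovery in the real comparisons. Of 110, 111 and 110 calls in these simulations 9, 14 and 14 were false, each a share above the threshold of 0.05.

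Genes called in ZM895 against both susceptible cultivars in the same direction were counted beside the number expected from independent lists and the number in 20 simulated data sets of unchanged groups that share the ZM895 libraries. With 2 libraries per group no other split of the samples could give a share under 0.05, so none was counted.

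The comparisons, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. The 26 lists are matched by words in the gene descriptions: pathogenesis-related proteins, NLR receptors, receptor kinases, WRKY factors, NAC factors, the salicylic acid, jasmonate and ethylene pathways, phenylpropanoids and lignin, oxidative burst and detoxification, diterpenoids and benzoxazinoids, cytochrome P450, sugar transport and cleavage, fructan, photosystems, Calvin cycle, chlorophyll breakdown and senescence, heat shock and chaperones, circadian clock, cytosolic ribosome, cell division, epidermis and wax, vascular tissue, storage and seed, transposon-like genes, and the window of 2A from 700000000 to 720000000 bp. That window was set from memory of where YR86 was mapped, and nothing in the files tests its limits. Chromosomes and GO and KEGG terms of 10 to 500 tested members were tested in the same way. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over its family within a comparison. For each list the members called over all genes and adjusted over the list alone were counted. GO and KEGG terms were tested at the preset correlation only.

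The rule named, per comparison and direction, the 8 called genes with the largest log2 difference among those with an absolute difference of at least 1, no overlap between libraries, at least 5 FPKM in the higher cultivar and an informative description. It added the called member of each list with the largest difference in each direction, the most abundant member of each list, the 6 genes per direction farthest from both susceptible cultivars, at most 10 genes of the 2A window called against both, and every tested NLR gene of that window. The 6 genes per direction had to meet, in both comparisons, the same conditions as the 8.

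Alternatives changed the filter on low values (none, or 5 FPKM), the scaling (median-ratio factors, libraries scaled to the same sum of FPKM, or quantile normalization, which was run with limma and so changes the test as well), the pseudocount of the limma test, the variance model, a replicate block, the libraries in the fit, each library left out in turn, and the test (DESeq2 1.42.0). Chosen after seeing the data were the use of the limma test as an alternative and fits without the 100 most abundant genes or without chromosome blocks. A block is a bin of 20 Mb with at least 20 tested genes of which at least 30 percent were at least 10-fold lower in 1 cultivar than in both others by mean FPKM.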

Results

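Flag leaves of field-grown bread wheat carrying inoculum of the stripe rust fungus Puccinia striiformis f. sp. tritici were compared between the resistant cultivar ZM895 and the susceptible cultivars JM22 and MX169, with 2 libraries per cultivar. The series concerns the resistance gene YR86 on the long arm of chromosome 2A. Only 1 resistant cultivar was sequenced, so resistance cannot be told apart from any other property of ZM895, and all 6 libraries were labelled as inoculated, so a standing difference between cultivars cannot be told apart from a response. The labels do not say that replicates come from separate plants, so the p-values measure only the spread between samples. Levels are FPKM as mean ± SD, n = 2. A gene is called when its adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg over 43580 tested genes) is under 0.05. In all 320 calls of genes named by rule the libraries of the compared cultivars did not overlap. The rule itself required this of the genes picked by size of difference, so it is no separate support for them. Homoeologous copies share reads, so the value of 1 copy can hold reads of another.

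A set of receptor genes was read in ZM895 and had almost no reads in both susceptible cultivars. All cultivars were counted on the same gene models, so few or no reads need not mean low expression. The gene may also be absent or diverged in that cultivar. TraesCS6A02G000200, a wall-associated receptor kinase, a class of kinases that span the membrane and bind the cell wall, averaged 87.5 ± 25.3 FPKM in ZM895, 0.0179 ± 0.0254 in JM22 and 0 in MX169. Its count ratio over JM22 was 5107 (95% counting interval 1413 to 42175), and it was at least 2807-fold higher than in MX169. The receptor-like kinase gene TraesCS3B02G024500 reached 115 ± 9.36 FPKM in ZM895 against 0.0596 ± 0.0305 in JM22 and 0.0308 ± 0.0115 in MX169. TraesCS7A02G007400, annotated as RPM1, a nucleotide-binding leucine-rich repeat receptor (NLR) that recognises pathogen effectors inside the cell, averaged 24.8 ± 0.382 FPKM in ZM895, 0.0117 ± 0.000543 in JM22 and 0.0058 ± 0.00821 in MX169.

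Further genes high in ZM895 had other functions, apart from another receptor kinase gene. The pathogenesis-related protein 4 gene TraesCS6A02G403200, of a family of antifungal proteins, stood at 19.9 ± 3.81 FPKM in ZM895, at least 199-fold above JM22, with a count ratio of 164 (55.7 to 795) over MX169. TraesCS6B02G362200 (Cyclin-L1-1) and TraesCS5D02G394900 (a regulatory subunit of protein phosphatase 2A) averaged 6.42 ± 1.15 and 6.39 ± 0.788 FPKM in ZM895 and had no read in either susceptible cultivar, which bounds the differences from JM22 at 84.3-fold and 82.6-fold or more. TraesCS6A02G400700, annotated as the receptor kinase EFR, which senses bacterial elongation factor in Arabidopsis, had 9.84 ± 5.01 FPKM in ZM895 and no read elsewhere (at least 351-fold above JM22). Its calls were lost with DESeq2, at adjusted p of 0.0998 against JM22 and 0.0677 against MX169.

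Genes low in ZM895 against both susceptible cultivars were more numerous, and 3 of the 6 named by rule as farthest apart lay on 7A. TraesCS7A02G333700, encoding the translation initiation factor eIF1A, had no read in ZM895 and 60.5 ± 4.14 FPKM in JM22 and 57.0 ± 0.134 in MX169, at least 609-fold and 653-fold more. That gene, like the next pair, lies between 480 and 500 Mb of 7A, where 46 of 55 tested genes (83.6%) were at least 10-fold lower in ZM895 than in both other cultivars and the median log2 difference from JM22 was −8.87. Of the 46, 27 had no read in ZM895. A difference there is only a lower bound, so the size of that median is not exact. The golden 2-like transcription factor gene TraesCS7A02G339800, the tonoplast water channel gene TraesCS7A02G331300 (TIP2;3) and the kinase gene TraesCS7B02G461600 also had no read in ZM895, at least 467-fold, 404-fold and 659-fold below JM22. The thaumatin-like PWIR2 gene TraesCS7D02G551400, of the PR5 class of antifungal proteins, averaged 0.0839 ± 0.0567 FPKM in ZM895, 373 ± 170 in JM22 and 281 ± 188 in MX169. It lies between 620 and 640 Mb of 7D, where 27 of 78 tested genes were at least 10-fold lower in ZM895. The neighbour TraesCS7D02G551600, annotated as a 4-hydroxy-4-methyl-2-oxoglutarate aldolase, had no read in ZM895 (at least 331-fold below JM22). Pheophorbide a oxygenase, the enzyme that opens the chlorophyll ring during leaf yellowing, was lower in ZM895 as well: TraesCS4D02G309000 averaged 17.6 ± 0.0855 FPKM against 85.0 ± 18.9 in JM22 (log2 difference −2.25, adjusted p = 0.00137) and 111 ± 39.6 in MX169 (−2.85, adjusted p = 0.000354).

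**Figure D1:**
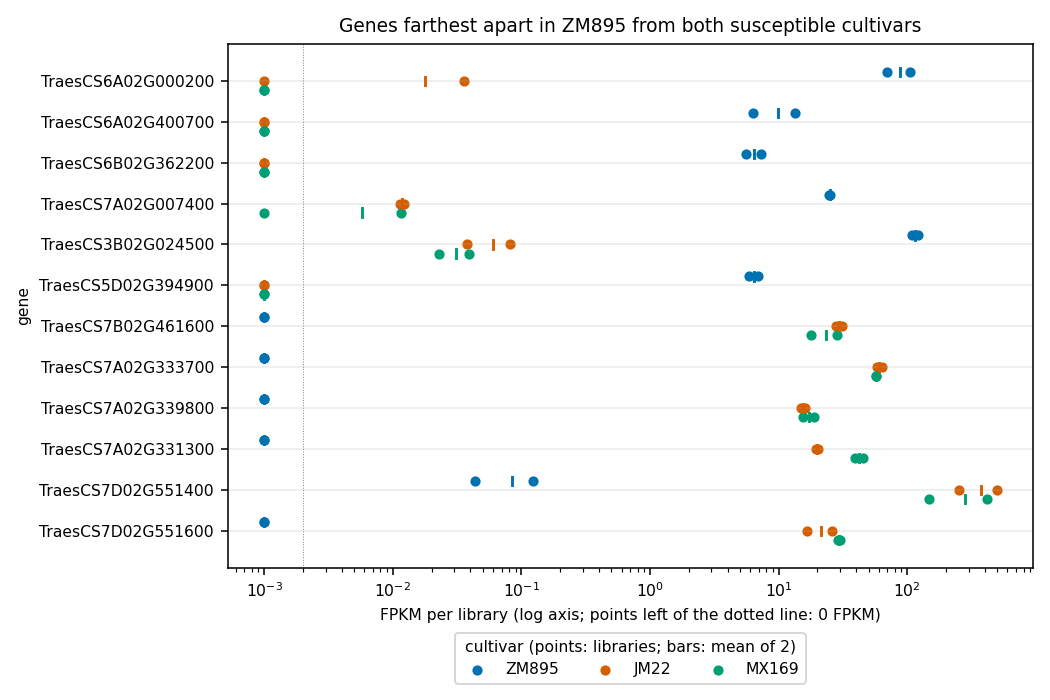
FPKM per library on a log axis for the 12 genes named by rule as farthest apart in ZM895 from both susceptible cultivars, with points for the 6 libraries, bars for the mean of 2, and libraries at 0 FPKM left of the dotted line. The rule took only called genes with an informative description, at least 5 FPKM in the higher cultivar and no overlap between libraries. Both ZM895 libraries lie above all 4 susceptible libraries for the first 6 genes and below them for the last 6.

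In total 920 genes were called higher and 1944 lower in ZM895 against both susceptible cultivars in the same direction. Independent lists of these sizes would share 273 and 386, and 20 simulated data sets with unchanged groups gave a mean of 0 higher and 0.2 lower. Unchanged groups show only what arises where no cultivar differs. Both comparisons use the same ZM895 libraries, which in the simulated groups gave a covariance of the log2 differences of 0.069, against 1.73 observed. Without ZM895 replicate 1 the number fell to 1610, and without JM22 replicate 1 to 1894. By the same rule JM22 had 684 genes higher and 1288 lower than both other cultivars, and MX169 had 2757 and 2341. Such sets were therefore not particular to ZM895. Tested against the mean of both susceptible cultivars, 4467 genes were higher and 4215 lower in ZM895. With libraries scaled to the same sum of FPKM that split was 5663 to 3559, and without ZM895 replicate 1 or replicate 2 the total of 8682 fell to 4027 and 5785. NLR genes had the lowest list p against the mean, with 137 of 540 higher and 46 lower (151 and 50 adjusted over the list alone), a median log2 difference of 0.22 and an adjusted p of 0.000268, or adjusted p = 0.787 with an estimated correlation. Against JM22 alone that list was not called (79 higher and 64 lower, median 0, adjusted p = 0.522), while against MX169 it was (148 and 66).

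The window from 700000000 to 720000000 bp of 2A, fixed in advance to hold the mapped region of YR86 as recalled from the literature, holds 326 genes, of which 107 were tested. Called against both susceptible cultivars were 1.9% higher and 5.6% lower in ZM895, beside 2.1% and 4.5% of all tested genes. The 2 called higher were TraesCS2A02G452100 with log2 differences of 1.17 and 1.23 and the ABC transporter gene TraesCS2A02G451300 with 0.89 and 0.90. The 6 called lower included TraesCS2A02G468500, a polyphenol oxidase, an enzyme that turns phenols into quinones (−3.35 against JM22 and −4.50 against MX169), and TraesCS2A02G467100, an FD-like gene of the family of flowering bZIP factors (−3.04 and −3.72). TraesCS2A02G466700 (−3.30 and −2.90), TraesCS2A02G479100 (−1.92 and −3.53), the aminomethyltransferase gene TraesCS2A02G467900 (−0.81 and −1.01), which serves photorespiration, and TraesCS2A02G477900 (−0.78 and −0.76) were the others.

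None of the tested NLR genes of the 2A window was called higher in ZM895 against both susceptible cultivars. The window holds 17 NLR genes in the annotation, and only 5 passed the expression filter. The others were not tested, and a resistance gene absent from the annotation would not be seen. TraesCS2A02G464600, annotated as RGA2, averaged 3.44 ± 2.36 FPKM in ZM895 and 4.05 ± 0.286 in JM22 but 0.0614 ± 0.0348 in MX169. TraesCS2A02G464400 stood at 5.33 ± 0.127, 9.36 ± 0.619 and 5.86 ± 0.688 FPKM in ZM895, JM22 and MX169, and TraesCS2A02G465000 at 7.0 ± 0.816, 12.2 ± 0.769 and 5.05 ± 1.15. TraesCS2A02G464900 averaged 2.43 ± 0.324 FPKM in ZM895, with no call in any comparison, and TraesCS2A02G480100 was lower in ZM895 than in JM22 (0.156 ± 0.0792 against 1.55 ± 0.052). As a list the window had 3 genes higher and 14 lower against JM22 (4 and 16 adjusted over the list alone, adjusted p = 0.0997), and 11 higher and 20 lower against MX169 (15 and 23 adjusted over the list alone, adjusted p = 0.605).

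Many calls over all tested genes were lost when single libraries were left out, and calls in this window were lost in the same way. Against JM22, those of TraesCS2A02G452100 (adjusted p of 0.0917 to 0.237), TraesCS2A02G477900 (0.0778 to 0.257) and the NLR genes TraesCS2A02G465000 (0.0906 to 0.242) and TraesCS2A02G464400 (0.0659 to 0.0985) were lost without any 1 of the 4 libraries compared. Those of TraesCS2A02G451300 (0.058 to 0.16) and TraesCS2A02G467900 (0.188 to 0.229) were lost without any of them but JM22 replicate 1. The calls of TraesCS2A02G479100 and TraesCS2A02G480100 were lost without ZM895 replicate 1 (0.0822 and 0.0621) or JM22 replicate 1 (0.0786 and 0.0515), and that of TraesCS2A02G468500 without JM22 replicate 2 (0.0521). Log2 differences stayed of the same sign, for example 0.98 to 1.40 for TraesCS2A02G452100. Other settings ended some calls too. A replicate block ended those of TraesCS2A02G452100 (adjusted p = 0.0718), TraesCS2A02G467900 (0.0939), TraesCS2A02G477900 (0.0824) and TraesCS2A02G465000 (0.0607) against JM22. Scaling libraries to the same sum of FPKM ended that of TraesCS2A02G477900 against MX169 (0.0845). Against MX169, TraesCS2A02G452100 lost its call without either ZM895 library or MX169 replicate 1 (0.0664 to 0.102), TraesCS2A02G477900 likewise (0.0523 to 0.153), TraesCS2A02G467900 without either ZM895 library (0.0718 and 0.0702), and TraesCS2A02G451300 without ZM895 replicate 1 (0.0888).

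**Figure D2:**
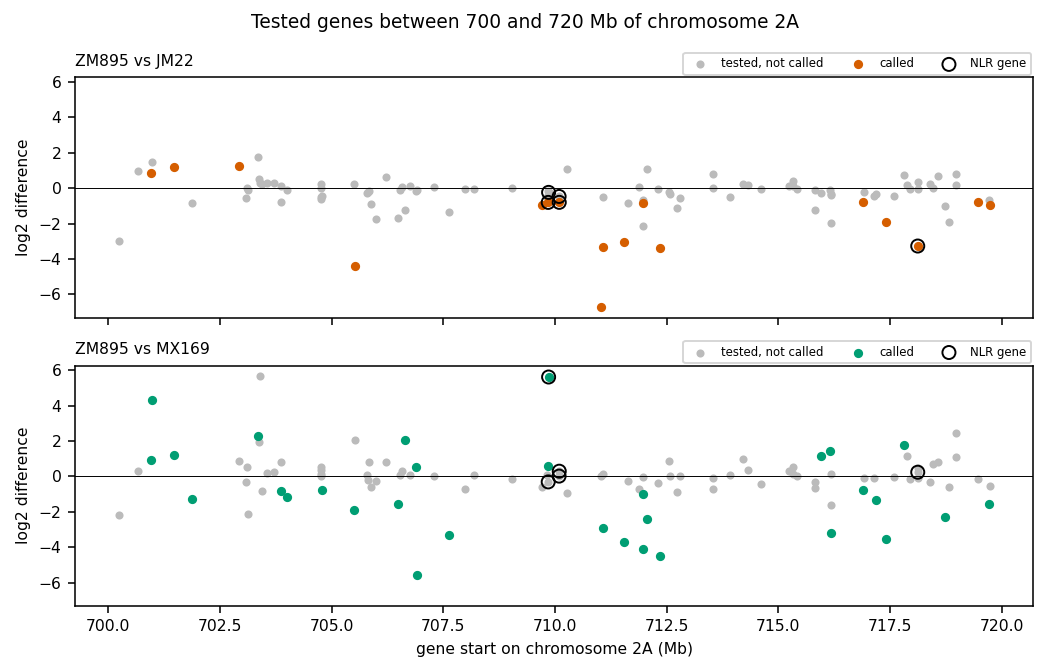
Log2 difference of the 107 tested genes by gene start in Mb between 700 and 720 Mb of 2A, for ZM895 against JM22 (top) and MX169 (bottom), with called genes coloured and the 5 tested NLR genes circled. Against JM22 3 genes were called higher and 14 lower, and against MX169 11 and 20.

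The longest run of low genes in ZM895 lay on chromosome 1B. From 0 to 220 Mb, 405 of 472 tested genes (85.8%) were called lower in ZM895 against both susceptible cultivars, and 283 (60%) were at least 10-fold lower. The median log2 difference there was −4.52 against JM22 and −4.46 against MX169, and −0.02 and −0.01 from 240 Mb on. Among these genes were the glutathione S-transferase gene TraesCS1B02G097200 (no read in ZM895, 17.8 ± 6.08 FPKM in JM22, at least 267-fold), of a family that detoxifies by adding glutathione, and the WRKY14 transcription factor gene TraesCS1B02G088900 (count ratio of JM22 over ZM895 1824, 327 to 72090). The ethylene receptor 1 gene TraesCS1B02G127000, which keeps ethylene responses off in the absence of the hormone, averaged 0.792 ± 0.116 FPKM in ZM895, 8.78 ± 1.93 in JM22 and 8.14 ± 0.104 in MX169.

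Over the whole of 1B, 102 of 1884 tested genes were higher and 542 lower against JM22 (158 and 602 adjusted over the list alone), and 173 and 665 against MX169 (217 and 694 adjusted over the list alone). It was the only chromosome called by camera in these comparisons, with adjusted p = 1.32e-14 and 9.61e-11, and the call held with an estimated correlation (adjusted p = 0.00966 and 0.0155). Between the susceptible cultivars 138 genes of 1B were higher in JM22 and 215 lower, with adjusted p = 0.987.

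**Figure D3:**
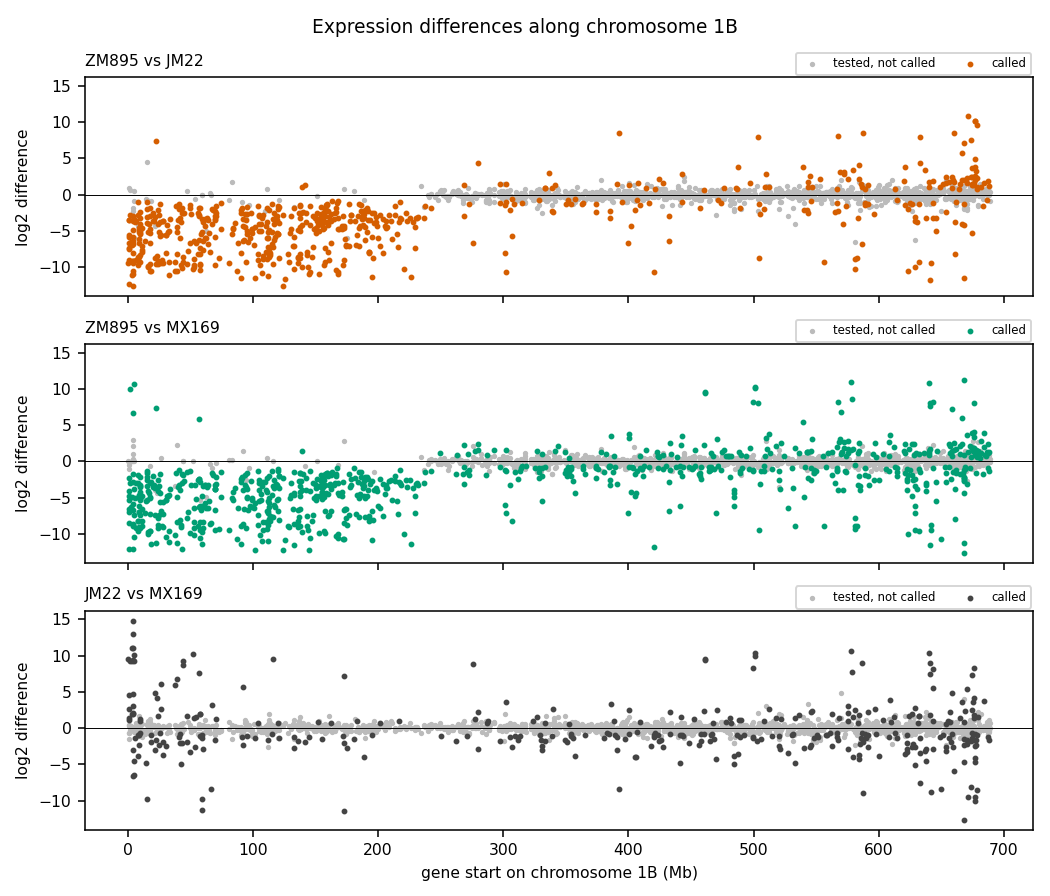
Log2 difference of tested genes by gene start in Mb along 1B in the 3 comparisons, with called genes coloured and other tested genes grey. Against JM22 and MX169 the genes of ZM895 from 0 to 220 Mb have medians of −4.52 and −4.46, and the JM22 against MX169 panel has no such segment.

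Genes far apart between ZM895 and JM22 included receptor and resistance genes. Higher in ZM895 were TraesCS7A02G018700, annotated as EFR, with 123 ± 28 FPKM against 0.0159 ± 0.0225 (count ratio 7539, 1353 to 297818), and the zinc transporter gene TraesCS2D02G506300, with 32.0 ± 2.77 FPKM against no read (at least 674-fold). It lies between 600 and 620 Mb of 2D, where 34 of 112 tested genes were at least 10-fold lower in JM22 than in both others. The NLR genes TraesCS7A02G021700 and TraesCS2B02G100200 (both annotated as RPP13) and TraesCS6B02G463700 (RPM1) averaged 7.78 ± 0.507, 17.1 ± 5.84 and 9.96 ± 1.55 FPKM in ZM895 and had no read in JM22, for bounds of 462-fold, 316-fold and 296-fold. The leucine-rich repeat kinase gene TraesCS2B02G082200 (25.8 ± 5.0 FPKM) was at least 295-fold higher than in JM22. The susceptible MX169 had reads of all of these as well. Its counts of the NLR genes were 3829, 670 and 47, beside 1584, 1083 and 1013 in ZM895. Those of the kinase gene were 126 beside 1010.

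JM22 had its own set. TraesCS7A02G039900, another RPM1-annotated NLR gene, averaged 147 ± 11.3 FPKM in JM22 with no read in ZM895 (at least 7129-fold), and the receptor kinase gene TraesCS1B02G006500 reached 77.8 ± 10.9 FPKM against 0.00917 ± 0.013 (count ratio 8163, 1465 to 322466), the latter in the low segment of 1B. In MX169, which had no such segment on 1B, the kinase gene had no read either, and the NLR gene had 1 count. TraesCS4A02G317500, a cysteine-rich receptor-like kinase, and TraesCS5B02G140300, encoding Cyclin-D3-1, which drives entry into the cell cycle, were at least 880-fold and 564-fold higher in JM22 than in ZM895. The wax gene TraesCS6A02G024400, a 3-ketoacyl-CoA synthase that lengthens fatty acids for wax, stood at 0.124 ± 0.134 FPKM in ZM895 and 120 ± 33.1 in JM22 (log2 difference −9.83, adjusted p = 1.58e-05).

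Between ZM895 and JM22, 2332 genes were higher and 2761 lower in ZM895, of which 1976 and 2457 changed at least 2-fold. The total fell from 5093 to 2954 without ZM895 replicate 1, to 3038 without JM22 replicate 1 and to 3323 without JM22 replicate 2. It was 8102 without a filter on low values and 2770 with a filter at 5 FPKM.

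Receptor lists had calls in both directions. Camera, which gave the adjusted p below, asks for a net shift of a list, which such calls can hide. Called were 26.5% of NLR and 27.5% of receptor kinase genes, beside 11.7% of all tested genes. The shares were 15.4% for pathogenesis-related proteins, 9% for WRKY factors and 14.6% for NAC factors. NLR genes were higher in 79 of 540 and lower in 64 (85 and 70 adjusted over the list alone; adjusted p = 0.522). Receptor kinases were higher in 101 of 810 and lower in 122 (128 and 147 adjusted over the list alone; adjusted p = 0.51). Pathogenesis-related proteins had 4 of 104 higher and 12 lower (4 and 14 adjusted over the list alone); their most abundant member, the PR1-1 gene TraesCS5B02G181500, averaged 258 ± 62.4 FPKM in ZM895, 457 ± 214 in JM22 and 455 ± 438 in MX169 with no call. WRKY factors, which regulate defence genes, had 2 of 111 higher and 8 lower (2 and 7 adjusted over the list alone), the lowest being the WRKY70 gene TraesCS7A02G338500 at 0.016 ± 0.0226 FPKM against 36.2 ± 15.9, in the low segment of 7A. NAC factors had 4 of 89 higher and 9 lower (6 and 14 adjusted over the list alone).

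Of all tested genes 11.7% were called between these cultivars, against 2.4% of the jasmonate, 14.3% of the salicylic acid and 22.2% of the ethylene list. Of 7 salicylic acid genes 1 was higher, the NPR1-annotated TraesCS7A02G021800 with 2.82 ± 0.413 FPKM against no read (at least 242-fold), and 0 were lower (1 and 0 adjusted over the list alone). The susceptible MX169 had 1899 counts of that gene, beside 828 in ZM895. The jasmonate list had 1 of 42 higher, the methyltransferase gene TraesCS3D02G256000 (log2 difference 2.44, adjusted p = 0.0262), and 0 lower (0 and 0 adjusted over the list alone). The ethylene list had 9 of 63 higher and 5 lower (10 and 6 adjusted over the list alone). TraesCS7D02G536900, encoding an enzyme annotated for the last step of ethylene synthesis, was 24.9 ± 4.68 FPKM in ZM895 and 70.7 ± 20.9 in JM22 (−1.49, adjusted p = 0.00755), in the low segment of 7D.

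Among defence metabolism lists, oxidative burst and detoxification genes were higher in 9 of 182 and lower in 33 (13 and 41 adjusted over the list alone), with an iron superoxide dismutase gene, TraesCS4A02G434000, at 19.9 ± 1.13 FPKM against 0.892 ± 0.293. Diterpenoid and benzoxazinoid genes were higher in 1 of 27 and lower in 7 (1 and 10 adjusted over the list alone), with TraesCS5B02G444600, an indole-3-glycerol phosphate lyase that releases indole, from which benzoxazinoids are made, at 0.39 ± 0.112 FPKM against 12 ± 7.39. Phenylpropanoid and lignin genes had 12 of 108 higher and 8 lower (13 and 12 adjusted over the list alone), and cytochrome P450 genes 5 of 123 higher and 17 lower (5 and 21 adjusted over the list alone). The cinnamyl alcohol dehydrogenase gene TraesCS6A02G369800, of the last step to lignin monomers, was 183 ± 19.2 FPKM in ZM895 and 34.1 ± 14.6 in JM22.

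The share called in primary metabolism and housekeeping lists ran from 6.5% in the ribosome list to 33.3% in the fructan list. Photosystem genes were higher in 4 of 157 and lower in 13 (4 and 13 adjusted over the list alone), Calvin cycle genes in 7 and 5 of 70 (7 and 7 adjusted over the list alone), and cytosolic ribosome genes in 9 and 11 of 309 (9 and 11 adjusted over the list alone). Chlorophyll breakdown and senescence genes had 0 of 13 higher and 3 lower (0 and 5 adjusted over the list alone). Sugar transport and cleavage had 6 higher and 10 lower of 82 (7 and 15 adjusted over the list alone), fructan metabolism 4 and 4 of 24 (5 and 4 adjusted over the list alone), and heat shock proteins 5 and 5 of 81 (5 and 6 adjusted over the list alone). Cell division had 17 higher and 12 lower of 190 (21 and 14 adjusted over the list alone), and the circadian clock 2 and 2 of 18 (3 and 6 adjusted over the list alone). The lowest clock gene was TraesCS1D02G451200 (early flowering 3-D1, a repressor of flowering), at 1.44 ± 0.298 FPKM in ZM895, 10.2 ± 0.00233 in JM22 and 9.51 ± 1.25 in MX169. It lies between 480 and 500 Mb of 1D, where 39 of 106 tested genes were at least 10-fold lower in ZM895.

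Of markers of other leaf tissues and of seeds, 14.9% were called in the epidermis and wax list, 16.7% in the vascular list and 10.5% in the storage and seed list. Epidermis and wax genes had 9 of 94 higher and 5 lower (10 and 6 adjusted over the list alone), vascular genes 1 of 6 higher and 0 lower (1 and 0 adjusted over the list alone), and storage and seed genes 0 of 19 higher and 2 lower (0 and 2 adjusted over the list alone). The single transposon-like gene tested, TraesCS2B02G292500, was 2.58 ± 0.0861 FPKM in ZM895 and 5.63 ± 2.61 in JM22, called lower only when adjusted over the list alone. Camera called 0 of the 26 lists between ZM895 and JM22, with 10 at an unadjusted p under 0.05 and an adjusted p of 0.0712 for the lowest, chlorophyll breakdown. Fry, which asks only whether a list moves one way, called 4 lists, all lower in ZM895: the 2A window (0.0388), diterpenoids and benzoxazinoids (0.0388), chlorophyll breakdown (0.042) and sugar transport (0.042).

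Between ZM895 and MX169 camera called 13 of the 26 lists at its preset correlation and 0 at an estimated correlation, where 3 were under an unadjusted p of 0.05. Phenylpropanoid and lignin genes, which make lignin and phenolic defence compounds, were lower in 54 of 108 and higher in 4 (56 and 9 adjusted over the list alone), with a median log2 difference of −1.19 and adjusted p = 5.4e-08, or adjusted p = 0.339 with an estimated correlation. Photosystem genes fell in 68 of 157 and rose in 2 (81 and 4 adjusted over the list alone; median −0.66, adjusted p = 1.7e-05, or adjusted p = 0.769 with an estimated correlation). The most abundant of them, the chlorophyll a-b binding gene TraesCS1A02G403300, averaged 2052 ± 47.3 FPKM in ZM895 and 3049 ± 41.9 in MX169. A different copy, TraesCS5B02G353200, ran the other way, at 641 ± 95.3 FPKM against 31.9 ± 3.96.

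Calvin cycle genes were lower in 25 of 70 and higher in 11 (33 and 11 adjusted over the list alone; median −0.49, adjusted p = 0.0273, or adjusted p = 0.849 with an estimated correlation). The small subunit gene of RuBisCO, TraesCS5D02G169900, which belongs to the enzyme that fixes carbon dioxide, averaged 3625 ± 134 FPKM in ZM895, 2486 ± 797 in JM22 and 7069 ± 408 in MX169. This list lost its call without ZM895 replicate 1 (0.0552), ZM895 replicate 2 (0.0798) or MX169 replicate 1 (0.0737), without the 100 most abundant genes (0.101) and with limma after quantile normalization (0.288). Chlorophyll breakdown and senescence genes fell in 7 of 13 and rose in 3 (8 and 3 adjusted over the list alone; median −1.28, adjusted p = 0.00236, or adjusted p = 0.445 with an estimated correlation). Besides pheophorbide a oxygenase, the members that fell include TraesCS6D02G112200, a receptor-like kinase described as senescence-induced, at 0.135 ± 0.0644 FPKM in ZM895 and 3.09 ± 0.217 in MX169. Sugar transport and cleavage genes fell in 23 of 82 and rose in 2 (25 and 3 adjusted over the list alone; median −0.51, adjusted p = 0.00236, or adjusted p = 0.339 with an estimated correlation). The cell wall invertase gene TraesCS2D02G489200, which splits sucrose outside the cell, averaged 10.7 ± 0.524 FPKM in ZM895, 3.46 ± 0.847 in JM22 and 64.5 ± 6.16 in MX169.

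Oxidative burst and detoxification genes fell in 72 of 182 and rose in 16 against MX169 (82 and 19 adjusted over the list alone; median −0.67, adjusted p = 1.31e-05, or adjusted p = 0.349 with an estimated correlation). The most abundant, the catalase gene TraesCS4B02G325800, was 445 ± 0.136 FPKM in ZM895 and 420 ± 38.1 in MX169 with no call. Pathogenesis-related proteins were lower in 30 of 104 and higher in 9 (33 and 9 adjusted over the list alone), short of the threshold as a list at adjusted p = 0.0595. Among them TraesCS6D02G386800, a pathogenesis-related protein 4 copy, had no read in ZM895 or JM22 and 32.4 ± 27.7 FPKM in MX169, at least 444-fold more than in ZM895.

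The ribosome list rose in 108 of 309 members and fell in 11 (172 and 12 adjusted over the list alone; median 0.73, adjusted p = 3.82e-08, or adjusted p = 0.823 with an estimated correlation). Heat shock proteins and chaperones, which refold proteins, rose in 33 of 81 and fell in 5 (35 and 5 adjusted over the list alone; median 0.64, adjusted p = 0.000432, or adjusted p = 0.57 with an estimated correlation). Their most abundant member, the heat shock cognate 70 kDa gene TraesCS5B02G492500, averaged 342 ± 3.04 FPKM in ZM895 and 194 ± 13.0 in MX169.

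Immune receptor lists were higher in ZM895 than in MX169. NLR genes rose in 148 of 540 and fell in 66 (163 and 67 adjusted over the list alone; median 0.29, adjusted p = 0.00115, or adjusted p = 0.769 with an estimated correlation). TraesCSU02G177000 and TraesCS2A02G046700, both annotated as RPM1, averaged 222 ± 3.32 and 29.3 ± 1.96 FPKM in ZM895 and 0.0382 ± 0.0541 and 0 in MX169, the second at least 741-fold apart. The second lies between 0 and 20 Mb of 2A, where 54 of 142 tested genes were at least 10-fold lower in MX169 than in both others. In the other direction the RPP13-like gene TraesCS2A02G029600 had no read in ZM895 and 22.2 ± 1.72 FPKM in MX169 (at least 776-fold). Receptor kinases rose in 245 of 810 and fell in 138 (282 and 151 adjusted over the list alone; median 0.39, adjusted p = 0.00817, or adjusted p = 0.849 with an estimated correlation). Their list call was lost without MX169 replicate 1 (0.313). Without a filter on low values the NLR and receptor kinase calls were lost too (0.0536 and 0.0692).

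Lists for other tissues also differed from MX169. Epidermis and wax genes fell in 29 of 94 and rose in 10 (33 and 12 adjusted over the list alone; median −0.60, adjusted p = 0.0364, or adjusted p = 0.349 with an estimated correlation). This call was lost without MX169 replicate 1 (0.0737) or replicate 2 (0.075), without a filter on low values (0.0521) and with a filter at 5 FPKM (0.203). Storage and seed genes fell in 6 of 19 and rose in 0 (7 and 0 adjusted over the list alone; median −0.56, adjusted p = 0.0349, or adjusted p = 0.769 with an estimated correlation). The list holds late embryogenesis and dehydrin genes, which leaves also make under water stress, and TraesCS4B02G332800 averaged 258 ± 55 FPKM in ZM895 and 607 ± 19.8 in MX169. That list call was lost without ZM895 replicate 2 (0.0889) or MX169 replicate 1 (0.15) and with a filter at 5 FPKM (0.0727). Circadian clock genes fell in 9 of 18 and rose in 2 (9 and 2 adjusted over the list alone; median −0.64, adjusted p = 0.0451, or adjusted p = 0.769 with an estimated correlation). That call was lost without ZM895 replicate 1 (0.172) or MX169 replicate 1 (0.0743), without chromosome blocks (0.107), with libraries scaled to the same sum of FPKM (0.0579), and with limma at a pseudocount of 0.1 (0.054) or after quantile normalization (0.0544). The pseudo-response regulator gene TraesCS2D02G079600, of the family of the photoperiod locus Ppd, was 2.19 ± 1.08 FPKM in ZM895 and 18.4 ± 4.29 in MX169.

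Genes read in ZM895 but not in MX169 included the blue copper-binding protein gene TraesCS4B02G271800 (47.9 ± 0.434 FPKM, at least 479-fold), the MADS-box gene TraesCS2B02G281000 (30.7 ± 1.47 FPKM, at least 408-fold) and the flavin-containing monooxygenase gene TraesCS2A02G071600 (17.9 ± 1.76 FPKM, at least 404-fold). JM22 had reads of them too, with 3472, 932 and 427 counts beside 1992, 1698 and 1680 in ZM895. Read in MX169 and not in ZM895 were TraesCS1A02G034900, an obtusifoliol demethylase of sterol synthesis (40.5 ± 0.336 FPKM, at least 1308-fold), the cytochrome P450 gene TraesCS5D02G559300 (27.8 ± 0.177 FPKM, at least 881-fold) and the S-adenosylmethionine synthase gene TraesCS6B02G197300 (27.9 ± 1.88 FPKM, at least 791-fold). JM22 had 34 counts of the demethylase gene, beside 2832 in MX169, and no read of the cytochrome P450 and synthase genes.

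Between ZM895 and MX169, 5097 genes were higher and 6090 lower in ZM895, of which 3781 and 4731 changed at least 2-fold. With libraries scaled to the same sum of FPKM the split turned to 7893 higher and 4669 lower, and the median log2 difference of all genes moved from 0 to 0.22. The 20 most abundant genes took 8.2% and 7.25% of the counts of the MX169 libraries and 4.5% to 5.54% of those of the other cultivars. The total of 11187 fell to 5843 without ZM895 replicate 1 and to 6471 with a filter at 5 FPKM.

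**Figure D4:**
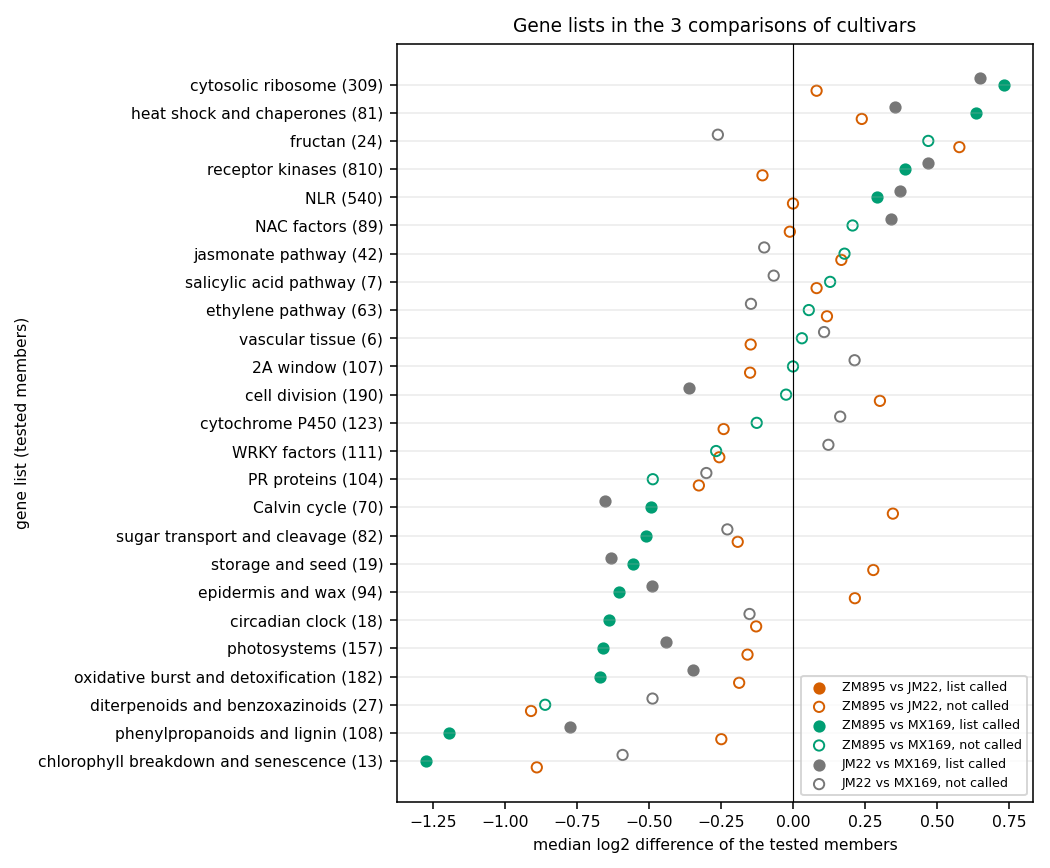
Median log2 difference of the tested members of each gene list with more than 1 member (number of members in brackets) in the 3 comparisons, with filled points for lists called by camera with the preset correlation and open points for the rest. Ribosome genes have medians of 0.73 and 0.65 in ZM895 and JM22 against MX169, and phenylpropanoid genes −1.19 and −0.78.

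JM22 differed from MX169 in many of the same lists, in a comparison that shares the MX169 libraries with the one before. Phenylpropanoid and lignin genes were lower in JM22 in 46 of 108 and higher in 2 (51 and 4 adjusted over the list alone; median −0.78, adjusted p = 1.58e-08, or adjusted p = 0.397 with an estimated correlation). The chalcone synthase gene TraesCS2D02G530600, which opens flavonoid synthesis, averaged 0.0138 ± 0.0194 FPKM in JM22 and 17.0 ± 9.49 in MX169, in the segment of 2D that was low in JM22. Calvin cycle genes fell in 35 of 70 and rose in 5 (39 and 6 adjusted over the list alone; median −0.65, adjusted p = 1.19e-05, or adjusted p = 0.662 with an estimated correlation). Photosystem genes fell in 40 of 157 and rose in 6 (56 and 8 adjusted over the list alone; median −0.44, adjusted p = 0.00194, or adjusted p = 0.662 with an estimated correlation). Oxidative burst genes fell in 48 of 182 and rose in 14 (55 and 16 adjusted over the list alone; median −0.35, adjusted p = 0.00481, or adjusted p = 0.662 with an estimated correlation). The oxidative burst call was lost without MX169 replicate 2 (0.0579).

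Cytosolic ribosome genes rose in 48 of 309 and fell in 6 in JM22 (43 and 6 adjusted over the list alone; median 0.65, adjusted p = 1.52e-08, or adjusted p = 0.662 with an estimated correlation). Heat shock proteins rose in 22 of 81 and fell in 3 (24 and 4 adjusted over the list alone; median 0.36, adjusted p = 0.00304, or adjusted p = 0.662 with an estimated correlation). Receptor kinases rose in 234 of 810 and fell in 117 (286 and 131 adjusted over the list alone; median 0.47, adjusted p = 0.000285, or adjusted p = 0.662 with an estimated correlation). NLR genes rose in 129 of 540 and fell in 75 (153 and 78 adjusted over the list alone; median 0.37, adjusted p = 0.00304, or adjusted p = 0.662 with an estimated correlation). The NLR call was lost without a filter on low values (0.099).

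Epidermis and wax genes fell in 27 of 94 and rose in 5 in JM22 (31 and 5 adjusted over the list alone; median −0.49, adjusted p = 0.00259, or adjusted p = 0.397 with an estimated correlation), a call lost with a filter at 5 FPKM (0.125). Cell division genes fell in 36 of 190 and rose in 9 (39 and 10 adjusted over the list alone; median −0.36, adjusted p = 0.0096, or adjusted p = 0.662 with an estimated correlation). Their call was lost without MX169 replicate 1 (0.0664) and without a filter on low values (0.0864). The histone H2A gene TraesCS1B02G296300 averaged 131 ± 11.7 FPKM in JM22 and 229 ± 32.2 in MX169. Storage and seed genes fell in 5 of 19 and rose in 0 (7 and 0 adjusted over the list alone; median −0.63, adjusted p = 0.0193, or adjusted p = 0.662 with an estimated correlation), lost with a filter at 5 FPKM (0.0634). NAC factors rose in 17 of 89 and fell in 12 (26 and 13 adjusted over the list alone; median 0.34, adjusted p = 0.0321, or adjusted p = 0.662 with an estimated correlation). This call was lost in 12 alternative settings, among them without ZM895 replicate 1 (0.0697), ZM895 replicate 2 (0.0717), JM22 replicate 1 (0.054) or MX169 replicate 1 (0.0924).

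Single genes read in JM22 and not in MX169 included the kinase genes TraesCS1B02G006500 (at least 1964-fold), TraesCS1B02G007400 (13.0 ± 3.95 FPKM, at least 585-fold) and TraesCS3A02G504700, annotated as FERONIA, a receptor of growth and immunity (17.5 ± 0.506 FPKM, at least 426-fold). The ent-copalyl diphosphate synthase gene TraesCS2A02G027800, which opens diterpenoid synthesis, averaged 14.5 ± 4.33 FPKM in JM22, 6.87 ± 0.0324 in ZM895 and 0 in MX169 (at least 440-fold below JM22), in the segment of 2A that was low in MX169. Read in MX169 and not in JM22 were the argininosuccinate lyase gene TraesCS5B02G299700 (36.7 ± 3.86 FPKM, at least 1068-fold), the wall-associated kinase gene TraesCSU02G230200 (43.7 ± 11.6 FPKM, at least 690-fold) and the jasmonate methyltransferase gene TraesCS5D02G560200 (29.6 ± 12.7 FPKM, at least 808-fold). The fructan 6-exohydrolase gene TraesCS2A02G488900, which breaks down fructan reserves, was 11.3 ± 0.623 FPKM in JM22 and 77.6 ± 8.89 in MX169 (log2 difference −2.97, adjusted p = 0.00127).

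Between JM22 and MX169, 3540 genes were higher and 4737 lower in JM22, of which 2728 and 3707 changed at least 2-fold. With libraries scaled to the same sum of FPKM the split turned to 6400 higher and 3496 lower, and the median of all genes moved from 0.02 to 0.26. The total of 8277 fell to 4000 without JM22 replicate 1, to 4465 without JM22 replicate 2 and to 4634 with a filter at 5 FPKM. Over the 3 comparisons camera called 25 lists with its preset correlation and 0 with an estimated correlation, where 5 were under an unadjusted p of 0.05, and fry called 15 lists, 9 of which were among the 25. None of the 25 calls changed direction under any alternative that was run.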

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

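Of the tests below, the gene length test was planned before its result was seen, and the tests on chromosome 1B, on the blocks, on the 5 settings of scaling and test and on the gap between lists were chosen only after the results were seen.

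Opposite effects of the same contrast were found for 237 genes, called in ZM895 in one direction against JM22 and in the other against MX169. Of these, 141 were higher than in JM22 and lower than in MX169, and 96 were the reverse. In all 237 both ZM895 libraries lay between those of JM22 and MX169. The difference was not tested apart from the calls that chose these genes, which all but fix the result of JM22 against MX169. The chromosomes with most of them were 2B with 31, 2D with 29, 3B with 19 and 5B with 17.

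The low segment of ZM895 on 1B is a regional pattern. Genes at 0 to 220 Mb of 1A and 1D were at least 10-fold lower in ZM895 in 23 of 1125 cases (2.0%), against 60% on 1B, which argues against depth or scaling. In 1000 shuffles of the low genes over all chromosomes at most 29.2% of the tested genes of a 20 Mb bin were low, against 44.8% or more in each of the 11 bins of 1B, which argues against low genes scattered singly. Of the 189 genes of the segment that were not 10-fold lower and so did not serve to delimit it, 2 (1.1%) were within 1.5-fold of both other cultivars, against 647 of 1366 (47.4%) beyond it, so a candidate explanation is a short arm of ZM895 that is lost or replaced against the reference, such as the rye arm carried by many bread wheats. Of the 283 genes of the segment that were at least 10-fold lower, 112 (39.6%) had no read in ZM895. The others kept some reads, which homoeologous copies can share. Loss, replacement and silencing of the arm were not told apart by these values.

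More genes were lower than higher in ZM895 against both susceptible cultivars, 1944 of 2864 (67.9%). The blocks as defined do not hold the whole excess. Outside them 1391 genes were lower and 896 higher, or 60.8% lower (exact 95% interval 58.8 to 62.8), and in them 553 were lower and 24 higher. The interval treats genes as independent, which genes of the same libraries are not. Smaller or partial low segments count as outside the blocks, so low segments as a cause of the rest were not excluded. A share of this kind may also arise for any single cultivar set against 2 others on a reference of another cultivar. That stays open: JM22 had 58.4% to 66.2% lower over 3 scalings of the count test and 54.3% with limma, but MX169 had 44.7% with median-ratio factors and 68.8% with libraries scaled to the same sum of FPKM, so the direction for MX169 rests on the scaling. ZM895 had more lower than higher genes under these 3 scalings, from 63.2% to 67.9%, and with limma, at 58.2%, or 59% after quantile normalization.

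Photosystem and phenylpropanoid lists were lower and the ribosome list higher in both ZM895 and JM22 than in MX169 at the preset correlation, but none of the 6 calls held with an estimated correlation (adjusted p = 0.769, 0.339 and 0.823 in ZM895 and 0.662, 0.397 and 0.662 in JM22). A few genes taking most of the counts of MX169 would shift all others by 1 factor, which alone would leave no gap between lists. The ribosome median lay at least 1.09 in log2 above the other medians (lowest 95% limit 0.99 in a bootstrap over genes). That limit leaves out the spread between libraries. These 3 lists were called in opposite directions before the test was chosen, so a gap was to be expected. Its size was not set against the spread between libraries. However the lists were chosen, 1 factor moves all of them alike. It alone cannot give medians of both signs, such as 0.73 for ribosome and −0.66 for photosystem genes in ZM895 against MX169. The 20 most abundant genes took 8.2% and 7.25% of the counts of the MX169 libraries, which is not most of them. These values argue against a few abundant genes as the only cause for these lists. The fit without the 100 most abundant genes moved little and decides nothing for them, while it ended the Calvin cycle call of ZM895 against MX169 (median −0.49, quartiles −1.14 and −0.01, to −0.44, −1.13 and 0.29; adjusted p = 0.101), with 12 of 70 members left out. Gene length is argued against, since length-matched genes outside the lists showed at most 1.7% of a list median. A difference in leaf age, growth stage or infection level of MX169 may underlie the pattern; these go with the cultivar, were not measured here and stay untested.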

How the results depend on the processing

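The alternatives chosen only after the data were seen were the limma test on log2(FPKM + 1) in place of counts and the fits without chromosome blocks or without the 100 most abundant genes. No call of a named gene or list changed direction, and of the genes called both here and under an alternative 0 changed sign. The balance of higher and lower calls did turn. For ZM895 against MX169 it went from 5097 higher and 6090 lower to 7893 and 4669 with libraries scaled to the same sum of FPKM, 7070 and 4933 with limma, and 5764 and 5524 with limma after quantile normalization, which change test and scale together. For JM22 against MX169 it went from 3540 and 4737 to 6400 and 3496 and, with limma, 5223 and 3774. Against the mean it went from 4467 and 4215 to 4732 and 4977 with DESeq2 and 2480 and 2509 at a filter of 5 FPKM. It turned there as well without ZM895 replicate 1 (2007 and 2020), ZM895 replicate 2 (2791 and 2994), JM22 replicate 1 (2999 and 3067) or MX169 replicate 1 (4390 and 4470). Without chromosome blocks ZM895 against JM22 had 2089 and 2065. The number of genes called was 8102 for ZM895 against JM22 and 4419 against both susceptible cultivars without a filter on low values. With a filter at 5 FPKM it was 2770, 6471 and 4634 for ZM895 against JM22, ZM895 against MX169 and JM22 against MX169, 4989 against the mean and 1621 against both, since 23618 genes were then tested. Leaving out 1 library at a time gave 2954 to 6456 genes for ZM895 against JM22, 5843 to 11865 for ZM895 against MX169, 4000 to 9924 for JM22 against MX169, 4027 to 10167 against the mean and 1610 to 3198 against both; the lone library is assumed to vary like the other groups. Counts moved over 1.5 times without ZM895 replicate 1 (2954, 5843, 4027 and 1610), ZM895 replicate 2 (5785 against the mean), JM22 replicate 1 (3038, 4000 and 1894) and JM22 replicate 2 (3323 and 4465); the cause was not tested. Of the 25 list calls, 0 held with camera at an estimated correlation. Fry, which asks another question, called 15 lists, of which 9 were among the 25. With replicate number as a block, the counts were 4026, 8958, 6221, 6822 and 2285; replicate numbers show no pairing, since deviations of replicates correlated between cultivars at −0.064, −0.038 and −0.166 across genes. The other alternatives, among them DESeq2 (6030, 11743, 9268, 9709 and 3338), limma (4891, 12003, 8997, 9023 and 2772) and the fit without blocks (4154, 10253, 7896, 7655 and 2181), stayed within 1.5 times. Over 129 results of single genes, 2671 checks gave 2544 on the same side of the threshold and 127 lost calls, and 97 results never lost theirs. Over the 25 list calls, 500 checks by camera at the preset correlation, which leave out the estimated correlation and fry, gave 461 and 39; the cause of the losses was not tested. Genes with a cultivar at 0 counts moved the median of a list by at most 0.126 when set to their bound (cytochrome P450, ZM895 against MX169).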

Other observations

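Every cultivar had segments of its own with low genes, by a search of 20 Mb bins chosen after the 1B segment was seen. Apart from the 11 bins of 1B, ZM895 was at least 10-fold lower than both others for 46 of 55 tested genes between 480 and 500 Mb of 7A, 39 of 106 between 480 and 500 Mb of 1D, and 27 of 78 between 620 and 640 Mb of 7D. In the 7A segment lie TraesCS7A02G333900, a caffeic acid O-methyltransferase of lignin synthesis with 0.0123 ± 0.0173 FPKM in ZM895, 27.1 ± 4.93 in JM22 and 45.9 ± 1.68 in MX169, and the ribosomal protein L27 gene TraesCS7A02G331700, with no read in ZM895. The 7D segment holds TraesCS7D02G549900, a dehydrin, a protein made under drought and cold, with no read in ZM895 and 5.33 ± 3.04 and 22.1 ± 5.37 FPKM in JM22 and MX169. JM22 was low for 34 of 112 tested genes between 600 and 620 Mb of 2D, with no read for 20 of them, among which is the zinc transporter gene TraesCS2D02G506300. MX169 was low for 54 of 142 between 0 and 20 Mb of 2A, with no read for 25, and this segment holds the ent-copalyl diphosphate synthase gene TraesCS2A02G027800, the ethylene synthesis gene TraesCS2A02G036900 and the RPM1-annotated TraesCS2A02G046700. Over the genome ZM895, JM22 and MX169 were at least 10-fold lower than both others for 1128, 791 and 887 genes and higher for 202, 221 and 470.

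GO and KEGG terms, tested by camera at the preset correlation, added groups outside the fixed lists; the terms were not tested with an estimated correlation, at which no fixed list was called. The water channel activity term, of aquaporins that pass water through membranes, had 0 members higher and 5 lower of 15 in ZM895 against JM22 (median −0.33, adjusted p = 0.0219) and 0 and 12 against MX169 (−1.11, adjusted p = 1.39e-08). In JM22 against MX169 it had 1 higher and 11 lower (−0.88, adjusted p = 0.00288). Serine-type endopeptidase inhibitors, a class of anti-feeding and anti-microbial proteins, were lower than in MX169 in ZM895 (0 higher and 18 lower of 33, median −3.17, adjusted p = 7.49e-07) and in JM22 (0 and 15, −2.14, adjusted p = 9.58e-06). The term for photoperiodism and flowering was higher than in MX169 in ZM895 (6 of 13, median 1.0, adjusted p = 3.94e-08) and in JM22 (6 of 13, 0.73, adjusted p = 2.69e-08). Gene silencing by RNA was higher than in MX169 too, in 22 of 67 members in ZM895 with 2 lower (0.40, adjusted p = 0.00355) and in 18 with 3 lower in JM22 (0.41, adjusted p = 0.00018). The KEGG term for diterpenoid biosynthesis was higher than in MX169 in ZM895 (10 higher and 1 lower of 28, median 0.85, adjusted p = 0.000127) and in JM22 (14 and 1, 0.82, adjusted p = 1.87e-07). The fixed list of diterpenoid and benzoxazinoid genes, matched by words, had in ZM895 3 higher and 10 lower of 27 (5 and 12 adjusted over the list alone, median −0.86, adjusted p = 0.734). In JM22 against MX169 that list had 9 higher and 5 lower (9 and 11 adjusted over the list alone, median −0.49, mean 0.71). Camera did not call it there (adjusted p = 0.265), while fry called it higher (adjusted p = 0.0422). Between ZM895 and JM22 the terms called higher were the U12-type spliceosome (6 higher and 0 lower of 22, adjusted p = 0.019) and protein refolding (5 and 1 of 38, adjusted p = 0.0219). In total 2 GO terms were higher and 2 lower in ZM895 than in JM22, 97 and 77 against MX169, and 41 and 78 in JM22 against MX169, of 1206 tested.

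Further lists were not called in ZM895 against MX169. The jasmonate list had 6 higher and 8 lower of 42 (7 and 9 adjusted over the list alone), with a median of 0.18 and a mean of −0.56 that differ in sign. WRKY factors had 4 higher and 9 lower of 111 (4 and 4 adjusted over the list alone), and NAC factors 16 and 17 of 89 (18 and 17 adjusted over the list alone). Cytochrome P450 genes had 19 higher and 35 lower of 123 (25 and 39 adjusted over the list alone), fructan genes 5 and 5 of 24 (7 and 5 adjusted over the list alone), and the ethylene list 8 and 13 of 63 (8 and 13 adjusted over the list alone). Median and mean also differed in sign for storage and seed genes (0.28 and −0.53), heat shock proteins (0.24 and −0.04), vascular genes (−0.15 and 0.33) and the circadian clock (−0.13 and 0.01) between ZM895 and JM22. The same held for the salicylic acid list (0.13 and −0.07) between ZM895 and MX169, and for the diterpenoid and benzoxazinoid list (−0.49 and 0.71) and the ethylene list (−0.15 and 0) between JM22 and MX169. The fructan 6-exohydrolase gene TraesCS2B02G516700 averaged 2.11 ± 2.57 FPKM in ZM895, 22.8 ± 4.55 in JM22 and 139 ± 6.06 in MX169, and the fructosyltransferase gene TraesCS7A02G009200, which builds fructan, 13.5 ± 9.01, 2.44 ± 1.60 and 0.127 ± 0.0599.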
